A study of Mus musculus with 4 samples.

How the data were processed

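RNA of 2 mouse cell lines, MBT2 (bladder cancer) and LM8 (osteosarcoma), was extracted in duplicate from untreated cultures, and the libraries were made from poly(A) RNA with a directional kit and read as 2 × 75 bases, per the labels' protocols. MBT2 grew in RPMI-1640 and LM8 in MEM with 24 mM HEPES, both with 10% serum, per the labels' protocols. The labels carry a number after a plus sign, 22 for MBT2 and 7 for LM8, whose meaning is not stated and which was not used. The 4 libraries were grouped by the cell line in their titles, with 2 libraries per line.

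The deposited tables are 1 list of sequence variants per line in variant call format 4.2. The unit of the deposited columns is reads per allele and library, with a caller's estimate of the allele fraction that was not used here. Both libraries of a line were called jointly with Mutect 2.2 and without a matched normal sample, per the file headers. The calls were filtered with FilterMutectCalls and passing records selected with SelectVariants of GATK 4.1.5.0, per the file headers, while the submitters' processing notes give GATK 4.3.0. Filter settings were at most 2 events in a region, at most 1 alternative allele, a median mapping quality of 30, a median base quality of 20 and an F-score beta of 1.0, per the file headers. One effect per variant was annotated with SnpEff 5.1d and database 105 of GRCm39, per the file headers. Reads were converted with bcl2fastq 2.17.1.14, trimmed with cutadapt 1.9.1 and aligned with STAR 2.7.9a to GRCm39, per the submitters' processing notes, which name the tools and not their roles, so the roles given here are the usual ones. How spliced reads were treated before calling is not given in the sources used here. A filter for sites scored as germline was among those applied, per the file headers, and almost no listed fraction lies between 0.4 and 0.6. Every record passed the filters and carried no known-variant identifier. A caller that starts from RNA lists variants only in expressed genes, and with no normal sample, differences between C3H/HeN mice and the reference strain can stay in the lists.

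The alternative-allele fraction was computed as alternative reads over reference plus alternative reads, summed over the 2 libraries of a line. Every site had at least 10 reads. Median depths per library were 62 and 61 reads in LM8 and 68 and 73 in MBT2. At 202 and 224 LM8 sites and 205 and 162 MBT2 sites, 1 library had no alternative read. Deletions of 21 or more bases were called long. A variant was shared when both lists had the same chromosome, position, reference and alternative allele, and private otherwise. Protein-altering variants were missense, stop gained, stop lost, start lost, frameshift, in-frame and splice site changes. Shares have exact Clopper-Pearson 95% intervals, and reads of amplified libraries are not independent molecules, so intervals cover counting error only.

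Substitutions were collapsed to 6 classes and compared between lines with Fisher's exact test per class and a Monte Carlo test over all classes with 100000 tables. Private variants per chromosome were compared with shared ones over 20 chromosomes. Genes with private protein-altering variants were compared with all genes with any listed variant for 10 gene lists fixed before the data were examined: cancer drivers (65 genes), chromatin regulators (44), DNA repair (48), antigen presentation (40), epithelial and urothelial genes (32), osteoblast and mesenchymal genes (36), markers of other cell types (24), cell cycle (32), housekeeping (20) and known targets of A-to-I editing (23). All tests were two-sided with Benjamini-Hochberg adjustment within a family and a threshold of 0.05. They count variants or genes of 1 list per line, so they compare the lists and not repeated cultures.

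Variants named in the text followed a rule fixed before the data were examined. It took private protein-altering variants in the lists of drivers, chromatin regulators, DNA repair and antigen presentation, up to 30 per line ordered by predicted impact and then depth. It also took the 10 genes per line with the most private variants and the 10 deepest private stop-gained or frameshift variants per line. Other names are said to be chosen after their values were seen. Some variants that the rule took are not reported here.

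The reference at hand, GENCODE release M21, is of the build GRCm38, so none of its coordinates was set beside those of the lists. It gave the strand of genes, the lengths of introns, and transcript sequences. The strand was matched by transcript identifier, or else by gene name, for 99.7% of genic LM8 substitutions and 99.8% of MBT2 ones. For long deletions, the length was compared with the introns of the same gene and with lengths 1 to 5 bases off them, and the deleted bases were searched for the ends of an intron, against shuffled bases.

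Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. The steps were tested on simulated data. In 200 simulated pairs of lists a C>A difference was called in 100% of pairs, and 5% of unchanged pairs had any class called. The pairs were drawn from the class shares of the real lists, so the first value shows only that a difference of that size is found. For chromosomes, 4.5% of unchanged lists had any call. Of 300 shared variants made, 300 were found, and 50.9% of 1000 deletions were at an exact intron length where 50.6% had been drawn from introns. The other simulated lengths reached far past the longest listed deletion (263 bases), so chance matches at the listed lengths were not measured there.

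Alternatives were a minimum of 20 reads, substitutions only, no A-to-G or T-to-C changes, no clustered variants, an allele fraction of at least 0.2, autosomes and X only, leaving out each library (at least 2 alternative reads in the other), a match on position only, genes listed in both lines only, truncating variants only, and genes as the base for chromosomes. Added after the data were seen were the lists without long deletions, without the alleles of the authors' germline resource (164 in LM8 and 178 in MBT2), and substitutions at a fraction of at least 0.1. Gene expression tests had been planned in case the files held expression values, and were not run because they hold variants. A burden per megabase was not computed.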

Results

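Sequence variants in messenger RNA were listed for 2 mouse cancer cell lines that are syngeneic with C3H/HeN mice. MBT2 is a bladder cancer line (clone label 63) and LM8 is an osteosarcoma line. Both were grown in culture without treatment, and 2 poly(A) RNA libraries were sequenced per line. The labels do not say whether the duplicates were separate cultures, so the spread between them may be technical. At the listed sites the LM8 libraries held 596298 and 571088 reads, with median depths of 62 and 61 reads per site. The MBT2 libraries held 742698 and 790762 reads, with median depths of 68 and 73. Across sites, which are not independent replicates, the alternative-allele fractions of the duplicate libraries had a Pearson correlation of 0.986 in LM8 and 0.988 in MBT2, and a lower Spearman correlation of 0.761 and 0.832. Fisher's exact test (two-sided) found a difference between duplicates at 0 sites in either line after Benjamini-Hochberg adjustment, and at 212 LM8 sites and 239 MBT2 sites at an unadjusted p under 0.05, which is 3.89% and 3.76% of the sites. Each line has 1 joint list of variants, so the reads of both libraries were summed per site. All confidence intervals are exact binomial 95% intervals and cover counting error only.

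The series asks how the mutational burdens of the lines compare. MBT2 had the longer list, with 6361 variants against 5445 in LM8. Single-base substitutions made up 49.8% of the MBT2 list (3169) and 51.5% of the LM8 list (2802). Deletions of 21 or more bases were the next largest type, with 2023 in MBT2 (31.8%) and 1633 in LM8 (29.99%). Insertions of a single base numbered 767 and 638, longer insertions 288 and 246, and deletions of 1 to 20 bases 114 and 126, with MBT2 given first. By annotated effect, 3′ UTR variants were the most frequent, with 1615 in MBT2 and 1401 in LM8, followed by upstream variants with 876 and 685. Long deletions matched spliced introns in length, as given in the closing section, so the counts below are also given without them.

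The lines shared 1261 variants with the same position and alleles, 23.2% of the LM8 list (22.0 to 24.3) and 19.8% of the MBT2 list (18.9 to 20.8). Most shared variants were not substitutions. Long deletions contributed 745 and single-base insertions 249, against 230 substitutions. Only 8.21% of the LM8 substitutions and 7.26% of the MBT2 substitutions were shared, against 45.6% and 36.8% of the long deletions. At shared sites the alternative-allele fractions of the lines correlated across sites with a Pearson r of 0.988 and a Spearman correlation of 0.916. Types with unlike fractions were pooled there, and the Spearman correlation was 0.746 within long deletions and 0.814 within substitutions. The remaining 4184 LM8 variants and 5100 MBT2 variants were private to 1 list. A private variant can also lie in a gene with too few reads in the other line, since only called sites are listed.

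**Figure D1:**
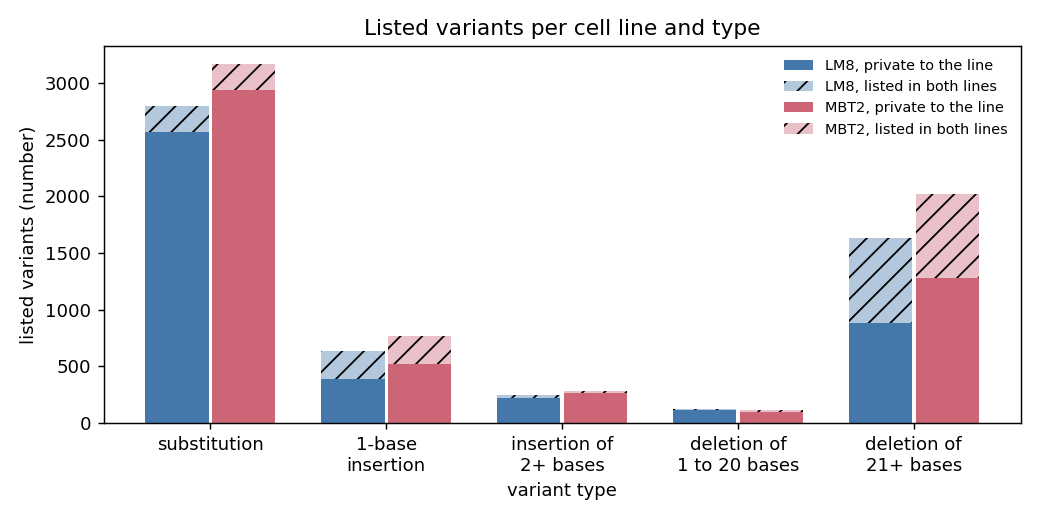
Bars give the number of listed variants (vertical axis) by variant type (horizontal axis) for LM8 and MBT2, with solid parts private to the line and hatched parts listed in both lines. Substitutions are mostly private (2572 in LM8 and 2939 in MBT2), while 745 long deletions are common to both lists.

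MBT2 carried more private variants that change a protein. The list held 1841 of them in 1441 genes, against 1365 in 1118 genes in LM8, a ratio of LM8 to MBT2 of 0.741 (95% interval 0.691 to 0.796). Missense substitutions numbered 721 in MBT2 and 603 in LM8, and stop-gained variants 43 and 21. Frameshifts numbered 540 and 371, of which 343 and 248 were long deletions, and splice site variants 519 and 354, of which 400 and 255 were long deletions. Single-base insertions made up 158 MBT2 and 96 LM8 private protein-altering variants, and longer insertions 107 and 96. The closing section gives the base repeats and transcript matches of listed insertions, and whether these insertions are mutations of the lines was not tested. With substitutions alone the counts were 795 in MBT2 and 634 in LM8, a ratio of 0.797 (0.717 to 0.886). The gap between the lines widened with the allele fraction: 234 MBT2 and 58 LM8 protein-altering substitutions had an alternative-allele fraction of at least 0.2, 4.03 times as many in MBT2 and a ratio of LM8 to MBT2 of 0.248 (0.183 to 0.332). The gap was smaller for all private substitutions at that fraction, with 705 in MBT2 and 354 in LM8. The intervals treat variants as independent counts. The counts were not adjusted for depth, and the median depth of listed sites was 141 reads in MBT2 and 124 in LM8. What part of the gap depth or the number of expressed genes accounts for was not tested. Fractions between 0.4 and 0.6 are nearly absent from both lists. Mutations on 1 of 2 equally expressed gene copies are thus largely missing from these counts. The ratio at higher fractions may therefore depend on copy number as well as on burden. Only MBT2 carries a clone label, so an effect of cloning on the fractions cannot be told apart from a difference between the lines. A rate per megabase was not computed, because a coding annotation of GRCm39 was not used here.

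Among tumour suppressor, oncogene, chromatin, DNA repair and antigen presentation genes, MBT2 had 71 private protein-altering variants in 44 genes and LM8 had 41 in 29 genes. Of these, 30 in MBT2 and 10 in LM8 were long deletions. Coordinates are GRCm39, counted from 1, and protein changes are numbered from the first residue of the transcript that the annotation chose. In MBT2, the p53 gene Trp53 had a splice acceptor substitution (chromosome 11, position 69479189) in 90.1% of 152 reads (84.2 to 94.4), at 89.7% and 90.5% in the 2 libraries. Splice site bases lie outside spliced RNA, so such shares cover only reads that kept them and not all RNA of the gene. The histone methyltransferase gene Setd2 had the stop-gained change E759* (chromosome 9, position 110447042, exon 10) in 67.3% of 300 reads (61.7 to 72.6). Hras, a small GTPase gene, had a splice donor substitution at 1.04% of 579 reads, and the DNA polymerase gene Pole had W1166* at 2.30% of 261 reads. The Pole change was G>A on the RNA strand, the form of 83.2% of the MBT2 C>T class under a fraction of 0.1. The rest of the first 30 MBT2 variants by predicted impact and depth were insertions or deletions. They included variants in the driver genes Eif4g1 and Tsc2, the chromatin genes Stag2, Atrx, Ncor1, Chd8, Asxl1, Kmt2b and Kmt2d, the repair genes Pold1, Fanca, Ercc3 and Recql4, and the antigen presentation and interferon genes Jak2, Ifnar2 and Psmb10. Those of Tsc2, Asxl1, Kmt2b, Kmt2d, Pold1, Fanca, Ercc3, Recql4 and Psmb10 were long deletions of intron length, so they may be spliced introns. Those of Eif4g1, Stag2, Atrx, Ncor1, Jak2 and Ifnar2 were at 0.268% to 4.22% of reads.

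In LM8, the highest substitution of this kind was a splice donor change of Nsd2, a histone methyltransferase gene (chromosome 5, position 34039513), in 84.9% of 53 reads (72.4 to 93.3). The limit given above for splice sites holds here too. The growth factor receptor gene Fgfr1 carried W101C (chromosome 8, position 26048208, exon 4) in 24.2% of 1006 reads (21.5 to 26.9), at 24.4% and 23.8% in the 2 libraries. Setd2 carried R457Q (chromosome 9, position 110377556, exon 3) in 20.9% of 129 reads (14.3 to 29.0). H2-Q4 carried R251K in 11.4% of 237 reads. Further LM8 substitutions among the first 30 were at 2.24% to 6.15% of reads: Map2k1 G213E, Myc L76R, Pold1 R222H, Pik3r1 G27R, Nsd2 A567T, Ezh2 C642W and Rad54l E470V. Those of Map2k1, Pold1, Pik3r1 and Nsd2 were G>A on the RNA strand, the form of 76.2% of the LM8 C>T class under a fraction of 0.1. Whether these are mutations of the line was not tested. Insertions and deletions among the 30 included some in the drivers Braf, Cul3 and Mdm4. Others lay in the chromatin genes Hdac1, Smc1a, Atrx, Chd8, Kdm6a and Chd3, the repair genes Recql4, Ogg1, Rad54l and Fanca, and Jak2. Those of Recql4 and of Fanca at position 124021794 were long deletions of intron length, so they may be spliced introns. Those of Braf, Smc1a, Mdm4 and Rad54l and the other Fanca variant were long deletions without a matching intron length. Those of Hdac1, Atrx, Chd8, Chd3 and Jak2 were single-base insertions of A or T, at 3.17% to 6.40% of reads. Those of Cul3, Kdm6a and Ogg1 were longer insertions.

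Some variants past the first 30 were chosen after their values were seen. MBT2 carried Trp53 C239Y (chromosome 11, position 69480019, exon 7) in 32.0% of 1088 reads (29.2 to 34.8). The phosphatase scaffold gene Ppp2r1a carried A147S in 32.1% of 1258 reads, the corepressor gene Ncor1 carried Y973C in 34.9% of 232 reads, and the acetyltransferase gene Crebbp carried E1551Q in 32.6% of 175 reads. H2-K1, which encodes a class I antigen presentation molecule, carried Y277N in 37.4% of 776 reads and Q285E in 29.6% of 443 reads. The H2 genes vary between mouse strains, and strain alleles were not told apart from mutations there. LM8 had no private protein-altering variant in Trp53, and it carried Notch1 L2200F in 21.2% of 52 reads and Msh3 A204T in 19.8% of 106 reads.

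The most deeply covered private stop-gained and frameshift variants were mostly in a small share of reads. In LM8 they lay in Panx3, Hsp90ab1, Arhgdia, Tardbp (2 variants), Anapc5, Slc39a7, Nolc1, Col12a1 and Arf1, at 0.2002% to 4.25% of reads except for Slc39a7, whose frameshift was a deletion of intron length in 90.1% of 1417 reads. Those of Panx3, Arhgdia, Anapc5 and Col12a1 and the Tardbp variant at 0.624% were long deletions too, that of Anapc5 of intron length. In MBT2 they lay in Eif4g1, Prkg2, Gnl3, Slc25a3, Spcs1, Col5a1, Psd, Cct5, Bop1 and Bzw1. The collagen gene Col5a1 had a single-base deletion (chromosome 2, position 27927018, exon 66) in 63.2% of 1546 reads (60.7 to 65.6), and Psd had a deletion of intron length in 14.7% of 1536 reads. The other MBT2 variants of this set were at 0.268% to 1.83% of reads. Among them, those of Prkg2, Gnl3, Slc25a3, Spcs1 and Bop1 were long deletions, of intron length in Prkg2 and Spcs1. Stop-gained substitutions at an allele fraction of at least 0.1, a limit chosen after the values were seen, numbered 7 in MBT2 (Setd2, Chpf, Nup155, Ptpn14, Fbln2, Tsc1 and Aifm2) and 2 in LM8 (Sema6b and Utp20).

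By number of private variants, the leading MBT2 genes were Nbeal2 with 16, Hjurp with 11, and Acadvl, Rnf123, Snx5 and Usp19 with 9 each. Col7a1, Kmt2b and Mib2 followed with 8 each. Long deletions made up 65 of the 95 variants in the 10 leading genes, including 14 of the 16 in Nbeal2. The 11 variants of Hjurp, a centromere chaperone gene, were all substitutions, at allele fractions of 0.0950 to 0.338. In LM8 the leading genes were Def8 and Sfi1 with 11 each, Rn18s-rs5 with 8, Arhgef39 and Wdr90 with 6 each, and Ankrd13d, Cul9, Gm37665 and Gm47652 with 5 each. Substitutions made up 43 of the 67 variants in the 10 leading LM8 genes, and all 6 variants of Wdr90 were deletions of intron length. Rn18s-rs5 is a copy of a ribosomal RNA gene, so its variants are uncertain because reads can come from other copies.

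No fixed gene list had an excess of genes with private protein-altering variants over the background of all genes with any listed variant. Fisher's exact test (two-sided, Benjamini-Hochberg over 18 tests) called 0 lists, and 1 list at an unadjusted p under 0.05. That list was the cell cycle genes in LM8, of which 13 of 21 genes with any variant (61.9%) had a private protein-altering one, against 32.0% of the background (exact test, p = 0.00772, adjusted p = 0.139), among them the kinesin genes Kif11, Kif20a and Kif23 and the kinetochore genes Cenpe and Cenpf. In MBT2 the same list had 4 of 18 (22.2%), against 36.6% of the background. For cancer drivers the counts were 8 of 22 in LM8 and 12 of 27 in MBT2, for chromatin regulators 11 of 24 and 14 of 25, for DNA repair 8 of 15 and 11 of 19, and for antigen presentation 2 of 11 and 7 of 13. Known targets of A-to-I editing had 5 of 11 and 6 of 12, osteoblast and mesenchymal genes 3 of 9 and 5 of 8, and housekeeping genes 1 of 5 and 4 of 7. None of the 32 epithelial and urothelial genes carried a listed variant in either line, and markers of other cell types had 0 of 1 in LM8 and 0 of 2 in MBT2. Without long deletions, an alternative chosen after the data were seen, the cell cycle list in LM8 passed the threshold (12 of 18, exact test, adjusted p = 0.0187).

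The spectrum of private substitutions differed between the lines, most in the class C>A. C>A changes made up 8.44% of 2939 private substitutions in MBT2 and 3.30% of 2572 in LM8 (odds ratio MBT2 to LM8 2.696, Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 6 classes, p = 2.07e-15). T>C was also higher in MBT2, at 44.9% against 39.97% (odds ratio 1.22, exact test, adjusted p = 5.06e-04). C>T was lower in MBT2, at 30.5% against 36.04% (odds ratio 0.777, exact test, adjusted p = 3.38e-05), as were T>G at 4.87% against 7.00% (0.680, adjusted p = 0.00126) and C>G at 3.78% against 4.94% (0.756, adjusted p = 0.0472). T>A was at 7.59% in MBT2 and 8.75% in LM8 (0.856, exact test, adjusted p = 0.126). Over the 6 classes together, a Monte Carlo permutation test with 100000 tables gave p = 1.00e-05, the smallest it can give.

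The C>A difference lay in substitutions at higher allele fractions. At fractions of at least 0.1, C>A made up 18.7% of 1022 MBT2 substitutions and 5.50% of 727 LM8 substitutions (odds ratio 3.95, exact test, adjusted p = 4.57e-16), and below 0.1 it made up 2.97% and 2.44% (odds ratio 1.23, adjusted p = 0.318). Private C>A changes had a median fraction of 0.285 in MBT2 and 0.0909 in LM8. The T>C difference lay below 0.1 (odds ratio 1.42, exact test, adjusted p = 7.13e-07). At fractions of at least 0.1, neither T>C (odds ratio 0.983, exact test, adjusted p = 0.877) nor T>A (1.22, adjusted p = 0.355) differed past the threshold. The tests count variants, not cultures, and C>G lost its call under 6 of the 14 alternatives.

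**Figure D2:**
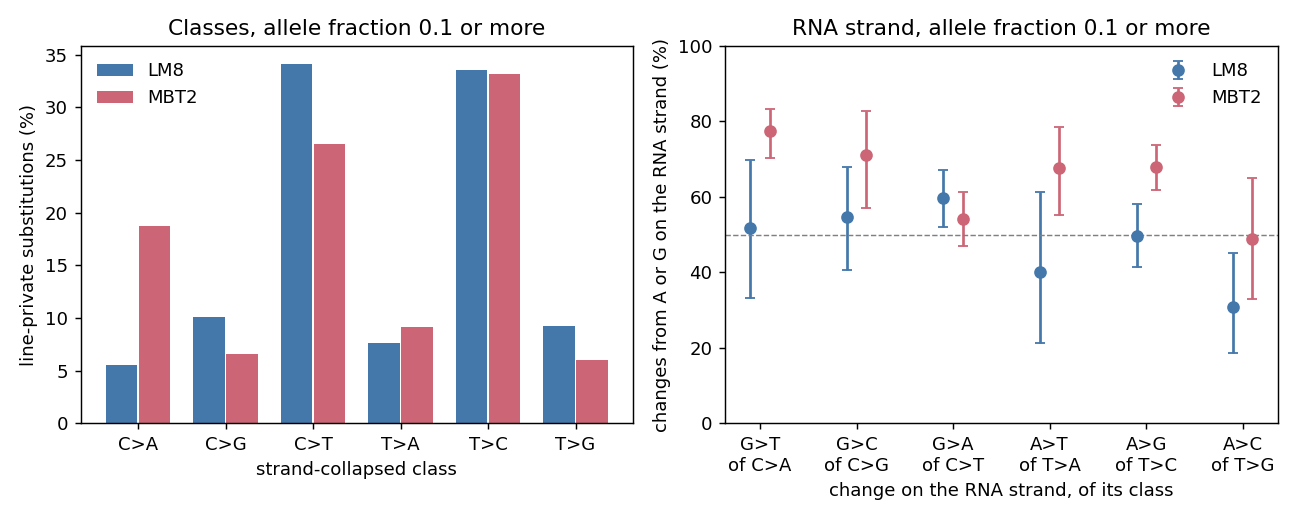
The left panel gives the share (%) of each strand-collapsed class among private substitutions at an allele fraction of at least 0.1, and the right panel gives, for each class, the share (%) in which the changed base on the RNA strand is A or G, with exact 95% binomial intervals. C>A stands at 18.7% in MBT2 and 5.50% in LM8, and 77.3% of the MBT2 C>A class are G>T on the RNA strand.

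Allele fractions differed between the types of variant, and more of the private substitutions of MBT2 than of LM8 were at higher fractions. Every listed site had at least 10 reads. The median fraction of private variants was 0.0732 in LM8 (quartiles 0.0386 and 0.248) and 0.0833 in MBT2 (0.0397 and 0.793), and that of shared variants was 0.726 in LM8 and 0.704 in MBT2, with upper quartiles of 0.889 and 0.867, a contrast that came from the mix of types: shared substitutions had medians of 0.0547 and 0.0557. Private long deletions had medians of 0.871 and 0.879, and private single-base insertions 0.0425 and 0.0408, with LM8 first. Private substitutions had medians of 0.0588 in LM8 and 0.0631 in MBT2, and 13.8% of them in LM8 and 24.0% in MBT2 were at 0.2 or more. The medians of private variants per library were 0.0730 and 0.0755 in LM8 and 0.0882 and 0.0892 in MBT2. Fractions between 0.4 and 0.6 were nearly empty, with 1 LM8 and 5 MBT2 variants of any type. The gap was wider at low depth: below 40 reads, substitutions stopped at 0.179 in LM8 and 0.162 in MBT2 and resumed at 0.842 and 0.848. RNA fractions also carry unequal expression of the alleles, which was not measured here. Only MBT2 carries a clone label, and an effect of cloning on the fractions was not tested.

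**Figure D3:**
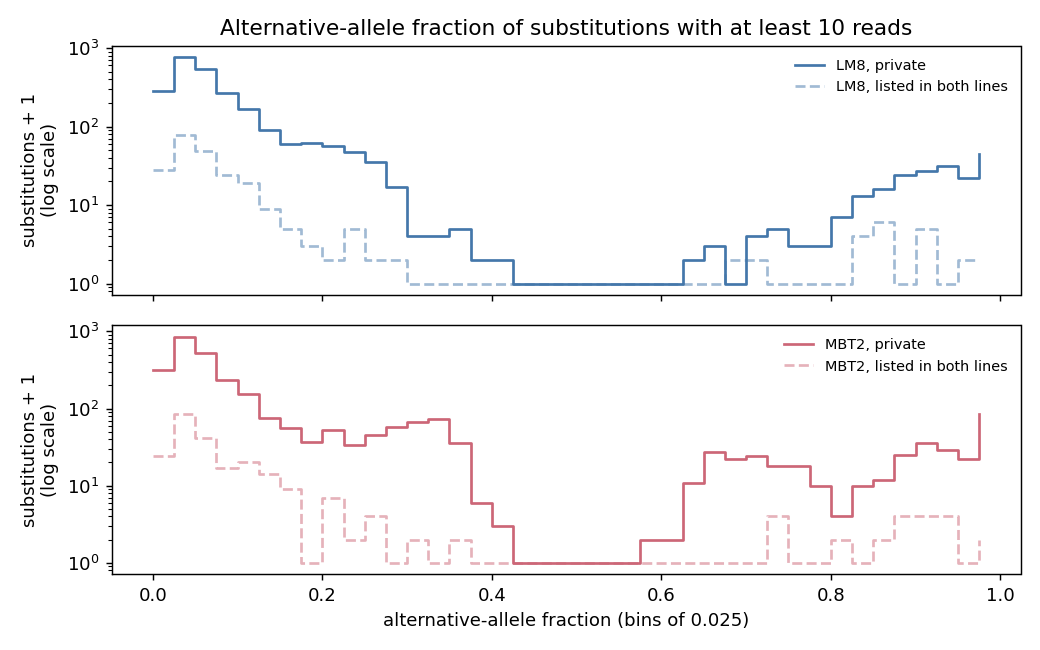
Lines give the number of substitutions plus 1 (vertical axis, log scale) in bins of the alternative-allele fraction (horizontal axis), solid for private substitutions and dashed for those listed in both lines. Both lines have an empty stretch around the middle, and MBT2 has a second rise with 72 private substitutions in the bin from 0.325 to 0.35, against 3 in LM8.

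The share of private variants per chromosome stayed close to that of shared variants. In LM8, 1 of 20 chromosomes passed the threshold: chromosome 19 held 4.03% of the private variants (168) and 6.29% of the shared ones (79; odds ratio 0.625, Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 0.0227). In MBT2, 2 chromosomes passed: chromosome 1 held 6.29% of the private variants (320) and 4.06% of the shared ones (odds ratio 1.59, exact test, adjusted p = 0.0347), and chromosome 17 held 5.84% (297) and 8.13% (odds ratio 0.701, adjusted p = 0.0347). All 3 calls were lost without long deletions and with genes in place of shared variants as the base. Outside these chromosomes, LM8 had 9 variants on Y (in Kdm5d and Gm47283) and 4 in mitochondrial tRNA genes, and MBT2 had 4 on Y (in Gm21693) and 5 in mitochondrial tRNA genes.

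A comparison chosen after the data were seen set private substitutions at fractions of 0.2 to 0.8 against those under 0.1. In MBT2, 9 of 20 chromosomes differed. Chromosomes 4, 10, 13, 14 and X held 1, 2, 0, 1 and 2 of the 490 substitutions at the middle fractions, against 96, 87, 63, 82 and 70 of the 1913 under 0.1 (Fisher's exact test, adjusted p from 1.52e-07 to 6.37e-05). Chromosome 11, which carries Trp53 and Ncor1, held 77 (15.7% against 8.78%, odds ratio 1.94, exact test, adjusted p = 6.37e-05), and chromosomes 2, 5 and 17 were also above their share (adjusted p = 0.00517, 0.0190 and 0.0190). In LM8 only chromosome 11 passed the threshold, with 28 of 176 (15.9% against 8.56%, exact test, odds ratio 2.022, adjusted p = 0.0496). Since variants near 0.5 are missing, the copy number of a chromosome may affect whether its mutations are listed at these fractions. Copy number was not measured, and its part in these differences was not tested.

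**Figure D4:**
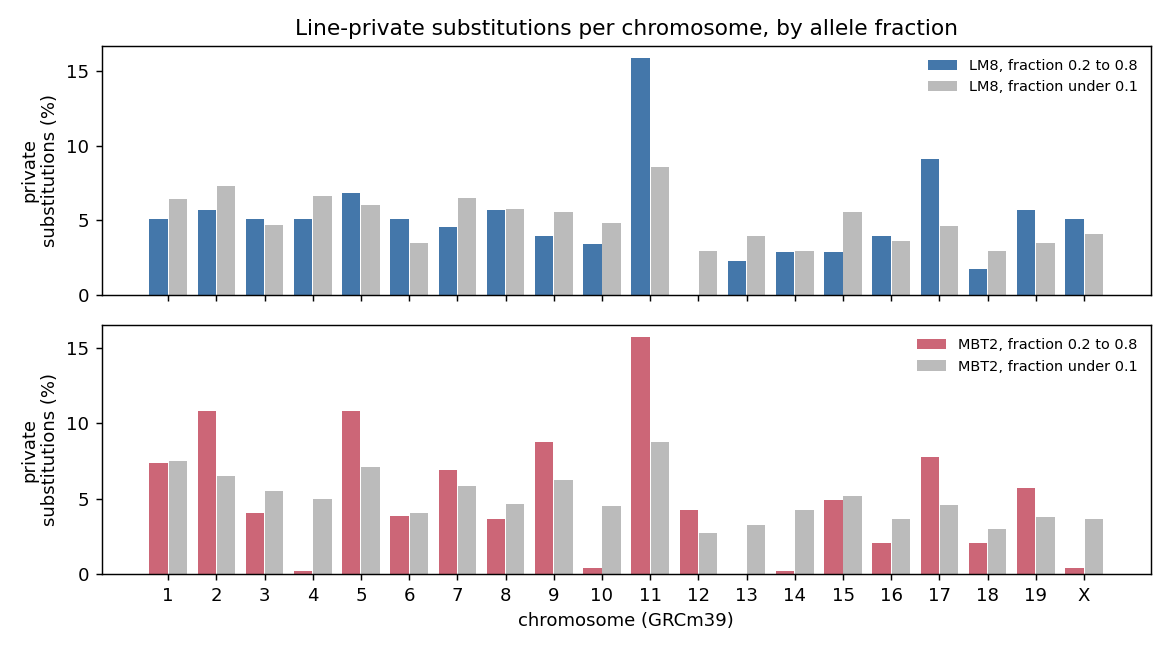
Bars give the share (%) of private substitutions per chromosome, LM8 above and MBT2 below, coloured for allele fractions of 0.2 to 0.8 and grey for fractions under 0.1. In MBT2 the coloured bars of chromosomes 4, 10, 13, 14 and X are at or under 0.408%, while chromosome 11 reaches 15.7%.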

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

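The split of substitutions by RNA strand, the alternative at a fraction of at least 0.1, and the tests of damage, base composition, strain variants and editing as the whole cause were chosen only after the result was seen, and the tests of transcribed-strand repair, editing for part of the sites and shallow sampling were fixed before theirs.

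Private substitutions at an allele fraction of at least 0.1 fell on the RNA strand differently in MBT2 and LM8 in 3 classes. In MBT2, 133 changes of the C>A class were G>T on the RNA strand and 39 were C>A (77.3%, 70.3 to 83.4), against 16 and 15 in LM8 (51.6%), an odds ratio of 3.20 (Fisher's exact test, adjusted p = 0.0205 over 6 classes). Of the T>C class, 174 were A>G and 82 T>C in MBT2 (68.0%), against 73 and 74 in LM8, an odds ratio of 2.15 (exact test, adjusted p = 0.00260). For the T>A class, 46 were A>T and 22 T>A in MBT2 (67.6%), against 10 and 15 in LM8, an odds ratio of 3.14 (exact test, adjusted p = 0.0377). The uneven strand was not limited to these classes or to MBT2: within MBT2, 37 of the C>G class were G>C and 15 C>G (71.2%, exact binomial, adjusted p = 0.00637), with no difference from LM8 past the threshold (adjusted p = 0.131), and within LM8 G>A made up 59.8% of the C>T class and A>C 30.8% of the T>G class (exact binomial, adjusted p = 0.0364 for both).

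For the G>T excess, damage to single RNA or cDNA molecules was examined in the whole C>A class and not in G>T alone. Of the 248 private changes of this class in MBT2, 64.9% (58.6 to 70.8) had a fraction of at least 0.2 with at least 2 alternative reads in each library, against 23.5% in LM8. Most of the class thus recurred in both libraries. This is no independent test of damage, because the class median of 0.285 was known and the excess was taken at fractions of at least 0.1. Base composition is argued against, since G made up 50.6% of the G and C bases of the transcripts concerned, below the interval of the G>T share. Strain variants stay open: the shares of the lines differed (exact test, p = 0.00684, with only 31 such changes in LM8), but only private substitutions were compared, so strain variants listed in both lines had been removed beforehand. Another candidate that stays open is guanine damage in the DNA with repair favouring the transcribed strand of expressed genes. The G>T share was 77.9% above the median depth of 235.5 reads and 76.7% below it (exact test, p = 1), which does not decide, and the different origins of the lines were not tested.

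For the A>G excess, a shallow sampling of reads is argued against, because at 40 or more reads 137 changes were A>G and 56 T>C (exact binomial p = 5.10e-09). A-to-I editing of the RNA may account for part of the sites, since a G stood before the changed A at 14.5% (6.50 to 26.7) of 55 coding sites against 30.2% of all A bases in the same codon places, and editing enzymes avoid that neighbour. A DNA change with the same preference was not tested. The 72 A>G sites of MBT2 in untranslated regions were outside this comparison, and no such share is given for LM8. LM8 also had A>G changes at known editing targets, as given below, without an excess (73 A>G and 74 T>C). The neighbouring base thus does not show why only MBT2 had the excess. Editing as the whole cause is argued against only weakly. The excess lay mostly at fractions of 0.2 to 0.8 (102 A>G and 16 T>C). There only 4 A>G changes (3.92%) were on the 5 chromosomes where the other classes were scarce. An excess that followed the 18% share of A>G changes under 0.1 would give 15.2%, or 10.3% at the lower 95% limits of both (exact binomial p = 0.0328 against the latter). The test took sites as independent although several can lie in 1 gene. Its base, A>G changes under 0.1, need not be edited sites. The different origins of the lines remain open here as well.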

How the results depend on the processing

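The alternatives without long deletions, without germline resource alleles and with substitutions at a fraction of at least 0.1 (and substitutions only, for allele fractions) were chosen only after the result was seen. No paired analysis was possible because the lines were compared through 1 list each, and the only test between libraries set the duplicates of a line against each other.

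The ratio of LM8 to MBT2 private protein-altering variants stayed below 1 in all 17 alternatives, from 0.531 to 0.797, and from 0.639 to 0.820 with a library left out. Leaving out a library shortened only the list of its own line. The latter range therefore shifts by construction and does not measure the spread between libraries. C>A, C>T and T>G kept their direction and call in all 14 alternatives, C>A with odds ratios of 2.65 to 4.94. Filters on passing records, on 10 reads and on clustered variants, and for the classes also the limit to substitutions, removed nothing and so show nothing.

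Counts fell by construction where types or fractions were left out. With substitutions only, LM8 and MBT2 had 2802 and 3169 variants, 230 shared, and 634 and 795 private protein-altering ones. At a fraction of at least 0.2 these were 1838 and 2572, 659, and 507 and 916, and for substitutions at 0.1 or more 782 and 1089, 45, and 155 and 292. Without long deletions 516 were shared and 853 and 1089 were protein-altering. Those 853 and 1089 still held single-base insertions (96 and 158) and longer ones (96 and 107). Genes listed in both lines held 673 and 847, and truncating variants were 746 and 1103. Leaving out a library gave 4785 to 4861 LM8 and 5721 to 5834 MBT2 variants, 1219 to 1235 shared, and 1176 to 1199 and 1664 to 1679 protein-altering.

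The C>G call was lost at 20 reads (odds ratio 0.760), without A-to-G and T-to-C (0.821), at a fraction of at least 0.2 (0.711), on autosomes and X (0.761), without germline resource alleles (0.781) and without MBT2 replicate 2 (0.789; range with a library left out 0.716 to 0.789). T>A reversed at fractions of 0.2 (1.31) and 0.1 (1.22) and passed the threshold without MBT2 replicate 2 (0.793; range 0.793 to 0.953). T>C reversed at 0.2 (0.992) and 0.1 (0.983), values close to 1, and at 0.1 neither class passed the threshold. For these classes the cause was not tested.

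Median allele fractions moved to 0.0588 (LM8 private), 0.0547 (LM8 shared), 0.0631 (MBT2 private) and 0.0557 (MBT2 shared) with substitutions only, and MBT2 private to 0.0811 at 20 reads. With a library left out they ranged from 0.0730 to 0.0755, 0.709 to 0.726, 0.0882 to 0.0892 and 0.684 to 0.692 in the same order; the cause was not tested. The chromosomes past the threshold, 1 in LM8 and 2 in MBT2, became 0 and 0 with genes as the base and 0 and 0 without long deletions, and the gene lists past it went from 0 to 1 without long deletions, where the cause was not tested.

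Not run were the alternative without known identifiers, because the records carry none, and all alternatives of gene expression, because the files hold variants.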

Other observations

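The tests of long deletions and the comparison of editing sites were chosen only after the result was seen.

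Known targets of A-to-I editing carried A>G changes at recoding sites. Cog3, a Golgi complex gene, had I635V (chromosome 14, position 75957159, GRCm39) in 84.8% of 46 LM8 reads (71.1 to 93.7) and in 21.5% of 130 MBT2 reads (14.8 to 29.6; Fisher's exact test, adjusted p = 1.32e-13 over 4 sites listed in both lines). The MBT2 libraries gave 24.6% and 18.8%. Azin1, which encodes an inhibitor of antizyme, had S367G (chromosome 15, position 38491856) in 3.39% of 620 LM8 reads and 4.15% of 1230 MBT2 reads (exact test, adjusted p = 0.598). Cdk13 had Q35R in 12.5% of 40 and 8.77% of 57 reads (exact test, adjusted p = 0.736). Listed only in LM8 were Igfbp7 K95R in 14.2% of 282 reads, Flna Q2333R in 13.0% of 138 reads and a 3′ UTR site of Mad2l1 in 67.1% of 425 reads, besides Cdk13 T166A (11.9% of 42 reads) and N177S (4.92% of 61), a synonymous site of Cog3 (6.67% of 45), 3′ UTR sites of Cds2 (12.5% of 40) and Son (4.55% of 66) and another of Mad2l1 (2.11% of 332). Listed only in MBT2 was a 3′ UTR site of Lactb2 in 31.9% of 188 reads.

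Low-fraction substitutions had a strand pattern of their own in both lines. Under a fraction of 0.1, G>A made up 76.2% of the C>T class on the RNA strand in LM8 and 83.2% in MBT2, and A>G made up 38.4% and 39.95% of the T>C class. Single-base insertions added A or T in 96.6% of cases in LM8 and 97.1% in MBT2, with a median of 6 repeat copies at the site. Of insertions of 20 or more bases, 150 of 200 in LM8 and 158 of 224 in MBT2 had a sequence found in a transcript of the same gene.

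Long deletions in genes such as Nbeal2, Wdr90 and Kmt2b may be introns removed by splicing rather than deletions in the DNA. Of the 1769 that lay in genes with annotated introns, 79.1% (77.2 to 81.0) had the exact length of an intron of the same gene, against 8.63% at lengths 1 to 5 bases off. Deletions in the DNA as the source of all of them are argued against, because 93.7% (92.8 to 94.6) of 2911 had the base pairs of intron ends at their edges, against 5.36% of shuffled sequences. The median length was 94 bases and the longest 263. What stays open is the remainder without a matching length, and why reads from spliced RNA were called this way, since the treatment of spliced reads is not given in the sources used here.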
